A study of Mus musculus with 6 samples.

How the data were processed

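The samples were LSK CD150- cells sorted from the bone marrow of 6 mice, 3 homozygous for the floxed Cebpa allele and 3 that also carried Mx1Cre. Both genotypes received pIpC and were taken at day 18. The series' design text says that each mouse was hybridised separately, so replicates are separate animals. Controls lacked the transgene, so carrying Cre and losing Cebpa cannot be separated here. Per the labels' protocols, 20 ng of total RNA was amplified with the Ovation Pico WTA kit and 2.5 µg of the amplified cDNA was fragmented and biotin-labelled. The arrays were 1-colour Affymetrix Mouse Gene 1.0 ST arrays.

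The authors deposited log2 values per probe set. RMA, which corrects background, normalizes between arrays and summarises the probes of each set, and Affymetrix Expression Console 1.1.2 are named in the submitters' processing notes. The RMA settings and the annotation build are not given in the sources used here. The values of 35556 rows ranged from about 2.17 to 14.6, none were missing, and they were used as deposited. No detection calls were used here, so signal over background was judged only from the intensities.

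Rows were named through a table of the platform's annotation, in which 23410 rows have a gene symbol: 21789 name 1 gene, 1621 name several and 12146 are unnamed here. Of 19939 gene IDs, 19856 matched a RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was used only for names, chromosomes and gene order. Rows naming 1 gene gave 19938 genes. For the 999 genes with more than 1 row, the row with the highest mean over all 6 arrays was kept. No filter on dim rows was applied.

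Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust prior, no block), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 fold changes are deleted minus control, each given with its moderated standard error, and 95% intervals of folds come from the same fit. The prior had 5.52 degrees of freedom. Cebpa was also compared with an exact permutation test.

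Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it, and members past the threshold were counted over all genes and adjusted over the list alone. Of 32 lists with 910 entries, 806 entries were measured, and 31 lists were testable. That of the mitochondrial genome had 0 measured genes. The lists were written from general knowledge of blood cells and pathways, and some genes belong to several lists. Fisher's exact test, two-sided, compared the changed genes with each list in each direction. The spread over chromosomes was tested with 100000 random draws, and neighbouring changed genes with windows of 50 genes and 10000 shuffles, in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

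The groups, the tests of genes, lists and chromosomes, the lists, the alternatives except the one named below as added, and the rule for named genes were fixed before the data were examined. The windows of neighbouring genes and the classes of short RNAs were added later. The rule took Cebpa, the 8 largest rises and the 8 largest falls among changed genes with non-overlapping genotypes, up to 3 members with the smallest p in the direction of each list that passed and 1 in the other direction where its unadjusted p was under 0.05, and the 2 members with the smallest p of 10 lineage lists. Left out of naming and of this ranking, but not of counting, were microRNAs, small nucleolar and other short RNAs, olfactory and vomeronasal receptors, symbols without a descriptive name such as clone names, and antigen receptor segments.

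The alternatives were an intensity trend or a robust estimate in the prior, filters at the 25th percentile and the median of mean intensity, quantile, median and cyclic loess normalization, the mean of all rows of a gene, every deposited row, the letters of the sample titles as a replicate block, array weights, other thresholds, an ordinary pooled-variance test and leaving out each array in turn. The list test was also run on ranks and without Cebpa, and, chosen after seeing the data, without Cebpa with an estimated correlation.

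Simulated data had variances drawn from the fitted prior, with genes drawn independently of each other. The gene and list tests were run on 20 such simulations of 19938 genes with 200 changed genes each. They recovered 14.6% of genes changed by 0.5, 90.0% of those changed by 1 and 99.5% of those changed by 2 on the log2 scale, and 5.51% of calls were false. A list lowered by 0.3 was called in 20 simulations, with 2 calls of other lists over all simulations. Because simulated genes were independent, these rates do not cover correlated genes. The errors were normal and followed the prior that limma itself assumes. A share of false calls near the threshold was therefore built in, and the simulations do not test that prior. The planted list was lowered evenly in all its members. The estimated correlation in the real lists reached 0.342, in the list of G2 and M phase. Rows naming several genes and unnamed rows were left out of the test of the 19938 genes. All deposited rows were fitted together in an alternative, and rows naming several genes were also fitted with the rows naming 1 gene.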

Results

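Gene expression was measured in LSK CD150- cells from mouse bone marrow. LSK cells lack markers of mature lineages and carry Sca-1 and Kit. They hold the blood-forming stem and multipotent progenitor cells, and the fraction without CD150, a surface protein of long-term stem cells, is depleted of the latter. The mice carried Cebpa alleles flanked by loxP sites. Cebpa encodes C/EBPα, a transcription factor of the granulocyte and monocyte lineages. In 3 mice the Mx1Cre transgene, switched on by the double-stranded RNA pIpC, deleted the gene, and 3 mice without the transgene were the controls. Cells of each mouse were sorted at day 18 after pIpC and hybridised to a separate Affymetrix Mouse Gene 1.0 ST array, so n = 3 per genotype. The comparison asks how the transcripts of these early progenitors differ once Cebpa is deleted.

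The median of all rows on the log2 scale lay between 6.22 and 6.23 on control arrays and between 6.16 and 6.20 on deleted arrays. The upper quartile (7.54 to 7.58 against 7.47 to 7.52) and the highest value (14.54 to 14.57 against 14.20 to 14.31) were also lower on deleted arrays. The arrays of the genotypes were thus not fully level at the bright end. Across genes, which are not independent replicates, Pearson's r between arrays was 0.989 to 0.990 among controls, 0.987 to 0.989 among deleted samples and 0.979 to 0.986 between the genotypes. The first principal component held 40.7% of the variance and separated the genotypes, with controls between -21.5 and -11.7 and deleted samples between 11.2 and 21.4. The number of arrays limits the precision of every value. The labels call the mice female, whereas transcripts of the Y-linked genes Kdm5d and Eif2s3y read between 8.04 and 8.49 on all 6 arrays, which argues against that label.

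Cebpa itself, on chromosome 7, fell 3.27-fold (95% interval 2.63 to 4.07) after deletion. Its mean was 7.80 ± 0.06 (SD, n = 3) in controls, with the mice at 7.84, 7.85 and 7.73, and 6.09 ± 0.27 (SD, n = 3) in deleted samples, with the mice at 6.37, 5.82 and 6.09. The values of deleted b and c lay below the median of all values, 6.20, so background may bear on this fold. The log2 fold change was -1.71 ± 0.14 (SE), with a limma adjusted p of 0.000883. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. Where the probes of this row lie relative to the deleted part of the gene is not given in the sources used here, so the fall checks the labels only as far as the row reads that part.

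A pair of other members of the C/EBP family of transcription factors rose. Of 6 measured members, Cebpg rose by 0.73 ± 0.12 (SE, adjusted p = 0.0240) and Cebpd by 0.55 ± 0.10 (SE, adjusted p = 0.0336), while Cebpa fell. Cebpb, with a log2 fold change of 0.70 ± 0.17 (SE), did not pass over all genes (limma adjusted p = 0.0909), nor did Cebpe (0.02) and Ddit3 (0.01). Adjusted over the list alone, 3 members were higher and 1 lower. The 2 higher genes over all genes tested exceeded the 0.0421 that chance would give (Fisher's exact test, adjusted p = 0.0112). The whole list did not pass camera, the competitive list test of limma (adjusted p = 0.425), but the 5 members other than Cebpa, with a median of 0.55, did (adjusted p = 0.0151, but adjusted p = 0.405 with an estimated correlation). The call of Cebpg was lost when control b or any deleted array was left out, with an adjusted p of up to 0.0881.

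**Figure D1:**
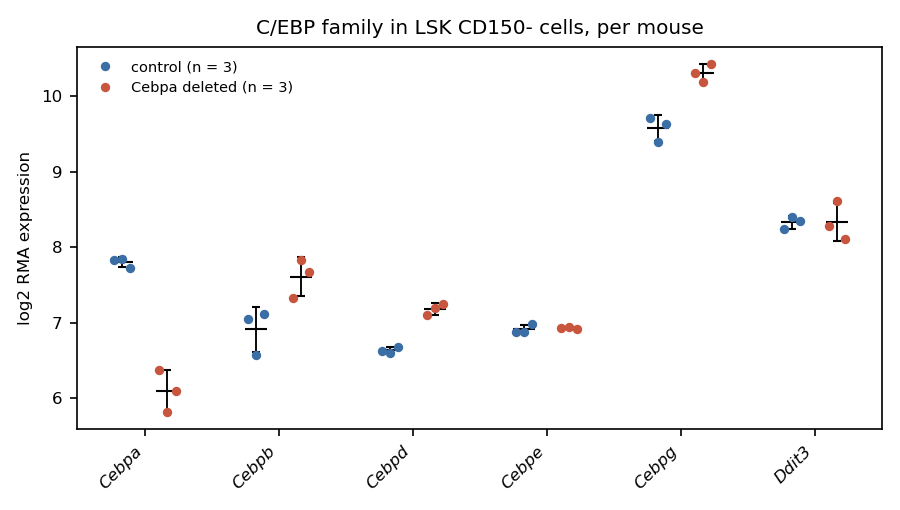
Log2 RMA expression (vertical axis) of the 6 measured C/EBP family genes (horizontal axis), with a point per mouse, a horizontal mark for the mean and bars for the SD, n = 3 per genotype. Cebpa lies at 7.80 in controls and 6.09 in deleted samples, and Cebpg and Cebpd lie higher in deleted samples.

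Among 19938 genes tested, 286 changed at an adjusted p under 0.05, with 140 higher and 146 lower after deletion. Of these, 66 changed at least 2-fold, 33 in each direction, and the median fold of the 286 was 1.71. Scin, which encodes an actin-severing protein, had the largest rise in the deposited values, 18.8-fold (log2 4.23 ± 0.25 SE), from 4.89 ± 0.22 (SD, n = 3) to 9.12 ± 0.58 (SD, n = 3). Cpa3, the carboxypeptidase of mast cell granules, rose 11.1-fold (log2 3.47 ± 0.12 SE). The calcium-binding proteins S100a8 and S100a9, abundant in neutrophils, fell 11.4-fold (log2 -3.51 ± 0.13 SE) and 10.3-fold (log2 -3.37 ± 0.17 SE). Their limma adjusted p-values were 9.3e-05 for Scin, 2.2e-06 for Cpa3 and S100a8, and 3.0e-05 for S100a9. Scin in controls (4.66 to 5.09) and S100a8 in deleted samples (4.74 to 5.03) read where signal was not separated from background, so their folds are ratios of deposited values only. S100a9 in deleted samples (5.50 to 6.08) also read below the median of all values, 6.20, so background may bear on its fold.

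Further large rises were those of Gzmb, a granule protease of cytotoxic cells (log2 2.20 ± 0.43 SE), Cst7, a cathepsin inhibitor (2.11 ± 0.16), the interferon-inducible genes Ifi209 (2.07 ± 0.29) and Ifi206 (1.59 ± 0.20), the signalling adaptor Sh2d1b1 (1.87 ± 0.31) and the short-chain fatty acid receptor Ffar2 (1.62 ± 0.16). The falls included Gsta4, a glutathione transferase (log2 -1.84 ± 0.21 SE), Tmem243 (-1.60 ± 0.16), the cytochrome Cyp2j6 (-1.58 ± 0.17), the transcription factor Etv5 (-1.53 ± 0.22) and Gdap10 (-1.50 ± 0.23). For each of these genes, as the naming rule required, and also for all 286, the 3 values of each genotype did not overlap. That was so for 21.2% of all genes, where chance gives 10%. Sh2d1b1 also read low in controls (3.96 to 5.18), where signal was not separated from background, as did Ifi209 in control b (4.97) and Etv5 in deleted c (5.04). Gzmb in controls (5.67 to 5.83), and Cyp2j6 (5.34 to 5.60) and Etv5 (5.04 to 5.80) in deleted samples, lay below the median of all values, 6.20. Gzmb varied most, with 9.24, 7.18 and 7.42 in the deleted samples. Its adjusted p was 0.0438 and reached 0.0507 with a robust prior and 0.0558 to 0.124 when any array other than deleted a was left out. Without deleted a its log2 fold change was 1.55. Sh2d1b1 lost its call without control a, deleted a or deleted b (adjusted p up to 0.0934), Ifi209 without deleted a or b (up to 0.0644), Etv5 without control b (0.0548) and Gdap10 without control a, control b, deleted b or deleted c (up to 0.0664). The log2 fold change of Etv5 lay between -1.68 and -0.94 over the alternatives.

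**Figure D2:**
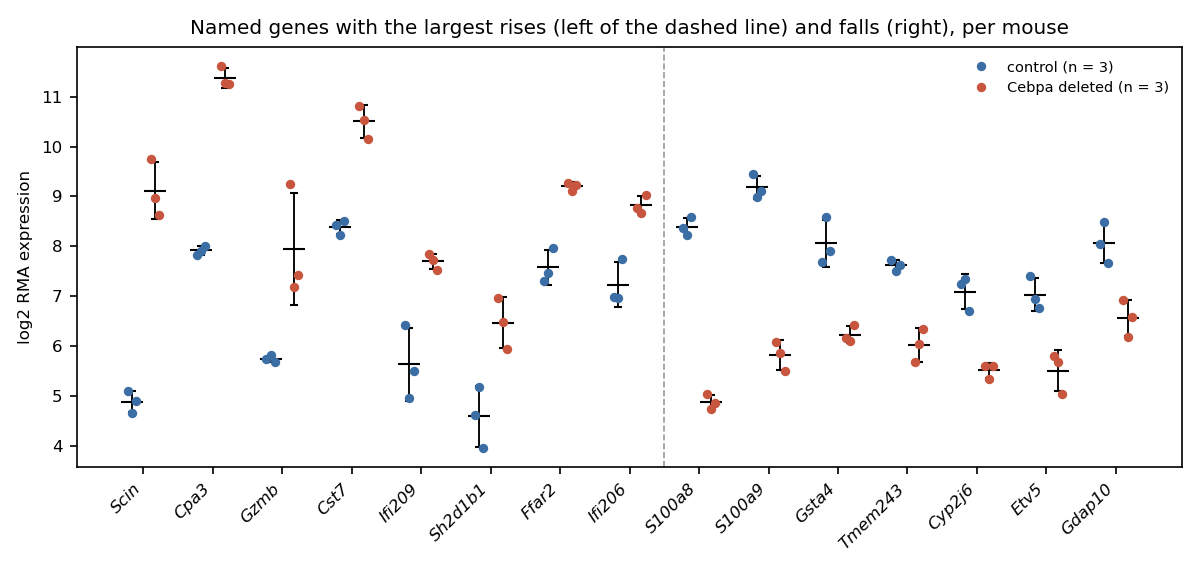
Log2 RMA expression (vertical axis) of the 8 genes with the largest rises and 7 of those with the largest falls, short RNAs and antigen receptor segments left out (horizontal axis; Cebpa has its own plot), with a point per mouse, a horizontal mark for the mean and bars for the SD, n = 3 per genotype. Scin goes from 4.89 to 9.12 and S100a8 from 8.39 to 4.88, and the genotypes do not overlap for any gene shown, as the naming rule required.

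The balance of directions differed between scalings: 49.0% of changed genes were higher with the deposited values and 49.0% after cyclic loess, against 61.6% after quantile normalization and 65.8% after centring each array on its median. The count of 286 became 126 without control a, 53 without control b, 145 without deleted a, 84 without deleted b and 143 without deleted c, 438 among genes at or above the median of mean intensity, 13 when every deposited row was tested, and 0 with an ordinary pooled-variance test per gene, which gave 2585 genes at an unadjusted p under 0.05 against 3164 with limma.

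Genes of haematopoietic stem cells were lower after deletion. Of 38 measured members of this list, 7 fell and none rose over all genes tested, and 14 were lower and 1 higher adjusted over the list alone. Mecom, a transcription factor needed to maintain stem cells, fell 2.77-fold (log2 -1.47 ± 0.14 SE, adjusted p = 0.00275), from 7.23 ± 0.23 to 5.76 ± 0.18 (SD, n = 3 each). Its values in deleted samples (5.61 to 5.96) lay below the median of all values, 6.20. Hlf, another stem cell transcription factor, fell 2.72-fold (log2 -1.44 ± 0.11 SE, adjusted p = 0.000744), and the surface receptor Procr 1.95-fold (log2 -0.97 ± 0.12 SE, adjusted p = 0.00854). The other members that fell were Trpc6 (-0.91), Meis1 (-0.89), Myct1 (-0.82) and Pdzk1ip1 (-0.64), a selection made after their values were seen. Ifitm1 had a log2 fold change of 0.67 ± 0.15 (SE) and did not pass (adjusted p = 0.0661), but did after quantile normalization (0.0420), after median centring (0.0492), with an intensity trend (0.0376), with the mean of all rows of a gene (0.0370) and among genes at or above the median of mean intensity (0.0446).

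The median log2 fold change of the stem cell list was -0.24, and camera gave an adjusted p of 2.7e-09 (adjusted p = 0.0920 with an estimated correlation). The 7 lower genes exceeded the 0.278 that chance would give (Fisher's exact test, adjusted p = 6.3e-07). Each array read the pooled sorted cells of a mouse. Fewer cells that express these genes and lower expression per cell therefore cannot be told apart.

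Genes of mature neutrophils were also lower. Of 20 measured members, S100a8, S100a9, Csf3r and Camp fell and none rose, with 7 lower and 2 higher adjusted over the list alone. Csf3r, the receptor of the granulocyte growth factor G-CSF, fell 2.13-fold (log2 -1.09 ± 0.20 SE, adjusted p = 0.0376), and Camp, an antimicrobial granule peptide, fell 1.95-fold (log2 -0.97 ± 0.16 SE, adjusted p = 0.0230). Cxcr2, a chemokine receptor, had a log2 fold change of 0.46 ± 0.13 (SE, adjusted p = 0.122). The list median was -0.22 (-0.97 for members at or above the median of mean intensity and -0.58 for those at or above the 25th percentile), with a camera adjusted p of 2.7e-05 (adjusted p = 0.0920 with an estimated correlation) and 4 lower genes where chance would give 0.146 (Fisher's exact test, adjusted p = 0.000378). Csf3r lost its call without any of the 3 controls, deleted b or deleted c (adjusted p up to 0.130), and Camp without control a, control c, deleted b or deleted c (up to 0.0915).

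**Figure D3:**
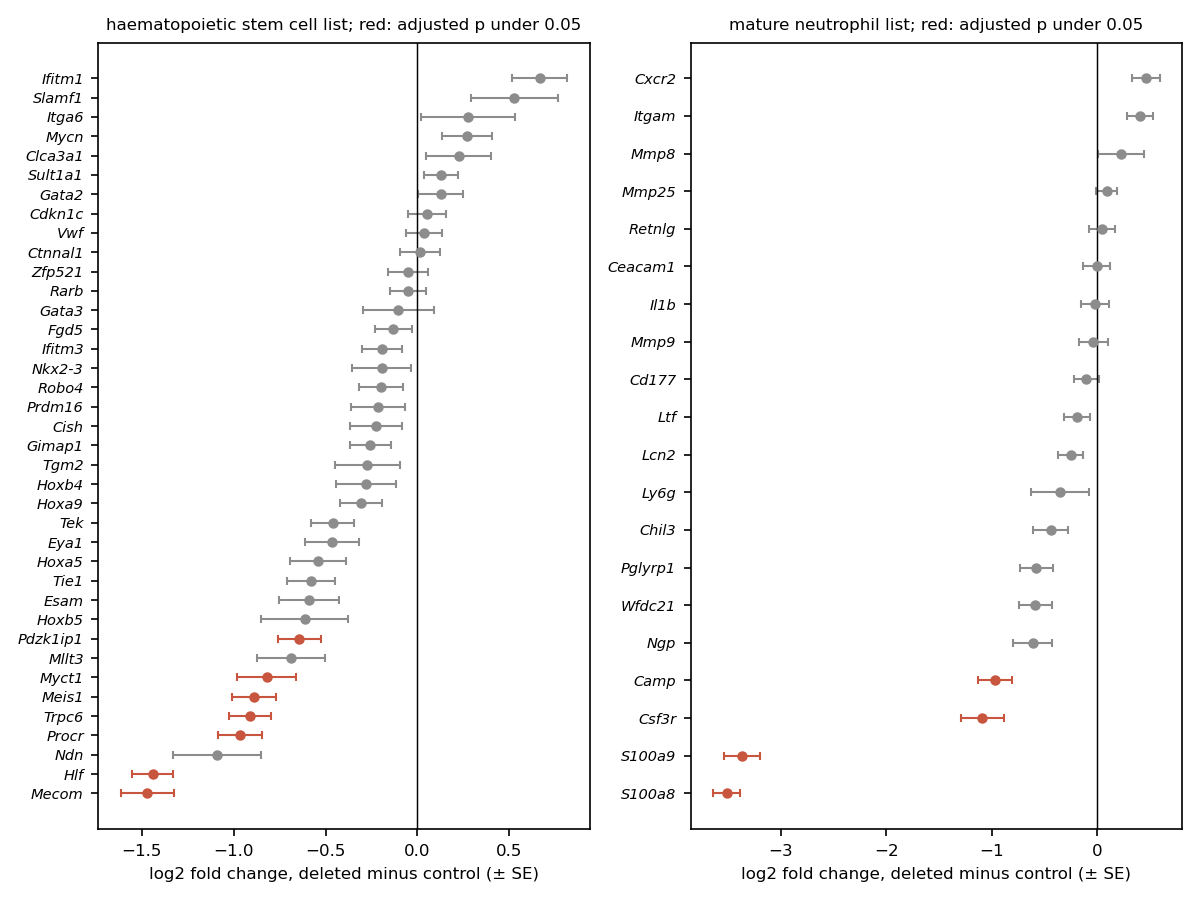
Log2 fold change, deleted minus control (horizontal axes), of each measured member of the stem cell list (left panel) and the mature neutrophil list (right panel), with bars for the SE of the limma fit to n = 3 mice per genotype. Red marks the 7 and 4 members past the threshold over all genes, which all lie below 0, with Mecom at -1.47 and S100a8 at -3.51 as the lowest.

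Of 24 genes of primary granules and neutrophil precursors, 1 rose and 2 fell. Serpinb1a, an inhibitor of neutrophil proteases, rose by 0.64 ± 0.10 (SE, adjusted p = 0.0151), while Mgst1 fell by 0.74 ± 0.12 (SE, adjusted p = 0.0215) and the lysozyme gene Lyz1, named after its value was seen, fell by 0.57. The list did not pass camera (adjusted p = 0.107), with 1 higher and 4 lower adjusted over the list alone. Of 25 genes of monocytes and macrophages, Cd68, a lysosomal membrane protein, fell by 0.90 ± 0.10 (SE, adjusted p = 0.00520) and Emb, named after its value was seen, fell by 0.70, while Tyrobp, an immune receptor adaptor, rose by 0.86 ± 0.13 (SE, adjusted p = 0.0165). That list did not pass (camera adjusted p = 0.584), with 2 higher and 3 lower adjusted over the list alone. Serpinb1a, Mgst1 and Tyrobp each lost their call when single arrays were left out, with adjusted p-values of up to 0.0664, 0.0840 and 0.0791.

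Of 18 myeloid cytokine receptors, 3 fell and none rose: Csf3r, Kit, the stem cell factor receptor (log2 -0.75 ± 0.13 SE, adjusted p = 0.0270), and Flt3, a receptor of early progenitors (log2 -0.71 ± 0.14 SE, adjusted p = 0.0469). These 3 exceeded the 0.132 that chance would give (Fisher's exact test, adjusted p = 0.00598), whereas camera did not call the list (adjusted p = 0.306), with 1 member higher and 3 lower adjusted over the list alone. The call of Flt3 was lost under quantile, median and cyclic loess scaling (adjusted p = 0.0582, 0.0511 and 0.0553) and without any array except deleted c (up to 0.145). Kit lost its call without any array except deleted a (up to 0.101).

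Ribosomal protein genes shifted downwards by a small amount. Of 41 measured genes of the cytosolic ribosome, 40 had a negative log2 fold change, with a median of -0.17, and Rps14 alone passed, lower by 1.47-fold (log2 -0.56 ± 0.11 SE, adjusted p = 0.0406; also 1 lower adjusted over the list alone). Rplp1 (-0.37 ± 0.10 SE, adjusted p = 0.106, or 0.0192 with an intensity trend) and Rps10 (-0.43 ± 0.12 SE, adjusted p = 0.121) did not pass. The camera adjusted p of the list was 1.2e-09 (adjusted p = 0.0920 with an estimated correlation). The list median was -0.05 under quantile normalization (camera adjusted p = 0.00167) and -0.10 under cyclic loess, and the call of Rps14 was lost with each of 3 other normalizations (adjusted p up to 0.0979) and when any single array was left out (up to 0.145).

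Of 20 genes of dendritic cells, Flt3 fell and none rose, with 3 lower and 1 higher adjusted over the list alone. The antigen presentation genes H2-DMa (-1.06 ± 0.23 SE, adjusted p = 0.0611) and H2-Aa (-0.84 ± 0.22 SE, adjusted p = 0.106) and the respiratory chain gene Cox6a2 (0.70 ± 0.18 SE, adjusted p = 0.1005) did not pass. H2-DMa passed without control c and among genes at or above the median of mean intensity (0.0417 in both), and Cox6a2 without deleted a (0.0313). The list median was -0.08 and the camera adjusted p 0.0307 (adjusted p = 0.269 with an estimated correlation), and the median moved between -0.30 and -0.03 over the alternatives. The call was also lost without control a (0.157), control c (0.0583) or deleted b (0.0521) and in genes at or above the 25th percentile of mean intensity (0.0534).

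These were the 4 of 31 testable lists that passed camera. With the directional test of fry 3 lists passed, all but that of dendritic cells (adjusted p = 0.0924), and 26 passed when members could change in either direction. Camera called up to 8 lists in other divisions of the 6 arrays into 3 and 3.

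**Figure D4:**
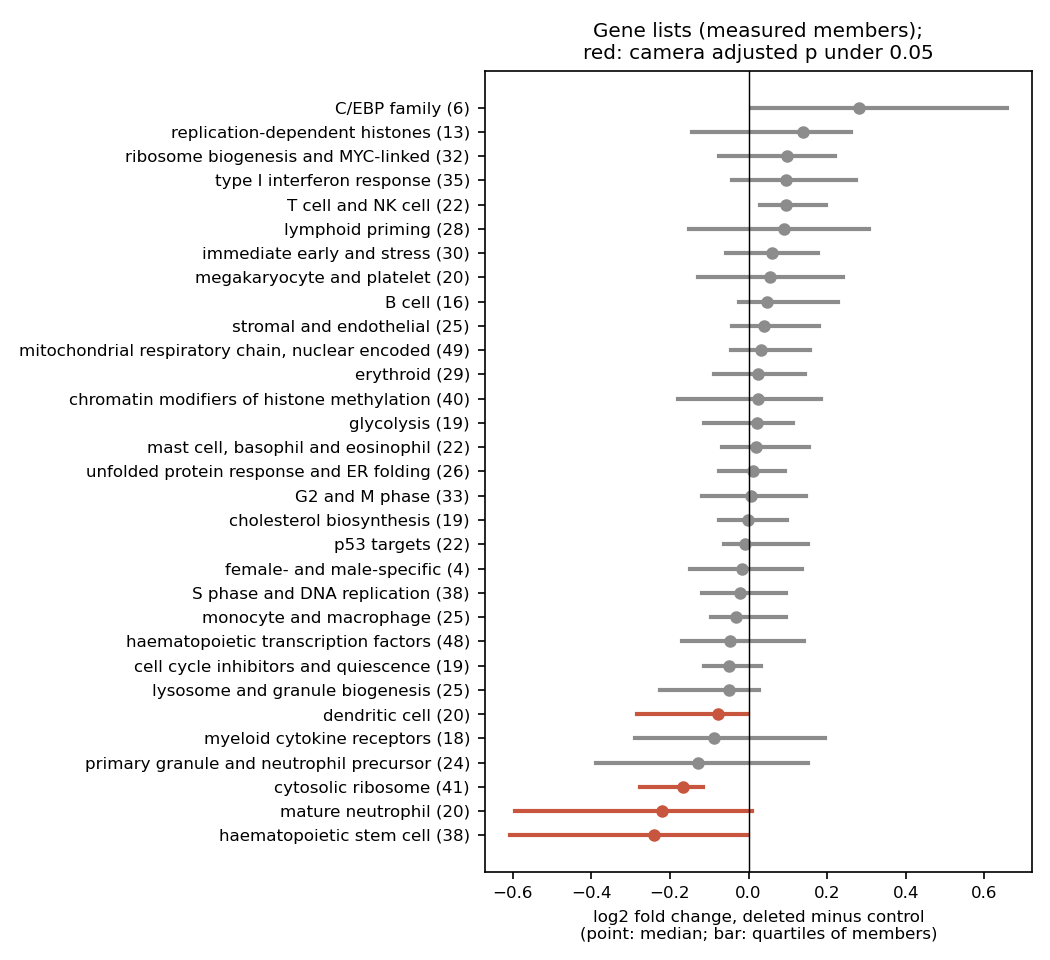
Median log2 fold change, deleted minus control (points), and quartiles of the members (bars, horizontal axis) for the 31 gene lists (vertical axis, measured members in brackets), from n = 3 mice per genotype. The 4 lists in red passed camera with a preset correlation, with medians of -0.24, -0.22, -0.17 and -0.08, and none passed with an estimated one.

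Among 22 genes of mast cells, basophils and eosinophils, Cpa3 and Gzmb rose and Kit fell, with 2 higher and 2 lower adjusted over the list alone and a camera adjusted p of 0.584. Other genes of these cells, named after their values were seen, did not pass: Mcpt8 (0.09), Ms4a2 (0.53), Fcer1a (-0.07) and Hdc (-0.02). Of 28 lymphoid priming genes, Arpp21 rose by 0.63 ± 0.12 (SE, adjusted p = 0.0337) and Flt3 fell, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.425). Dntt, the terminal transferase of lymphoid progenitors, also named after its value was seen, had a log2 fold change of 0.70 (adjusted p = 0.0688). Arpp21 lost its call without any array except control c (up to 0.115).

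Of 16 B cell genes Cd72 fell by 0.81 (camera adjusted p = 0.928, 1 higher and 1 lower adjusted over the list alone), and of 22 T and NK cell genes none passed (0.336, none adjusted over the list alone). None of 20 megakaryocyte and platelet genes passed (camera adjusted p = 0.836), where F2r (0.52 ± 0.11 SE, adjusted p = 0.0571) and Itga2b (0.44 ± 0.12 SE, adjusted p = 0.104) had the smallest p, with F2r past the threshold under quantile and median scaling and both intensity filters (0.0361 to 0.0453), and with 2 higher and 1 lower adjusted over the list alone. None of 29 erythroid genes passed either (camera adjusted p = 0.952), with Car2 at -0.47 ± 0.12 (SE, adjusted p = 0.0896) and Tfrc at 0.36 ± 0.11 (SE, adjusted p = 0.161), and none adjusted over the list alone. Of 25 stromal and endothelial genes Pdgfrb rose by 0.99 and Emcn fell by 0.97 (camera adjusted p = 0.584, with 3 higher and 2 lower adjusted over the list alone). Of 48 haematopoietic transcription factors Id2, an inhibitor of E proteins, rose by 1.44 and Meis1 fell by 0.89 (camera adjusted p = 0.425, 1 higher and 1 lower adjusted over the list alone). Cd72, Pdgfrb, Emcn and Id2 were named after their values were seen.

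Of 35 genes of the type I interferon response, Rtp4 rose by 1.03 ± 0.17 (SE, adjusted p = 0.0241), and Ifit1 (0.54 ± 0.12 SE, adjusted p = 0.0573) did not pass, although it did with each of 3 other normalizations and both intensity filters (0.0377 to 0.0493). The list had a median of 0.10 and a camera adjusted p of 0.185, with 4 higher adjusted over the list alone. It passed without deleted b (0.00531) or deleted c (0.0397). Rtp4 lost its call without control a, control b, deleted a or deleted b (up to 0.0781).

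No gene passed among 33 genes of G2 and M phase (camera adjusted p = 0.863) or 38 of S phase and DNA replication (0.386), and none adjusted over either list alone. In the limma fit, the median log2 fold changes of these lists were 0.01 and -0.02. Of 19 cell cycle inhibitors Txnip fell by 0.86 (0.336, 2 higher and 2 lower adjusted over the list alone). Of 32 ribosome biogenesis genes Pes1 rose by 0.72 (0.336, 1 higher adjusted over the list alone), and of 19 glycolysis genes Pfkfb3 rose by 0.65 (0.921, 1 higher and 1 lower). Of 40 genes in the list of chromatin modifiers Rnf2 rose by 0.51 (0.921, 1 higher and 2 lower). These 4 genes were named after their values were seen.

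No gene passed in the lists of immediate early and stress genes (30 genes, camera adjusted p = 0.336, 2 higher adjusted over the list alone), p53 targets (22, 0.695, 2 higher and 1 lower), the unfolded protein response (26, 0.921), the nuclear-encoded respiratory chain (49, 0.584), cholesterol biosynthesis (19, 0.943), lysosome and granule biogenesis (25, 0.185, 2 higher and 2 lower), histones (13, 0.754, 1 higher) or the sex-specific genes (4, 0.863). For the lists of G2 and M phase, glycolysis, chromatin modifiers, p53 targets, the unfolded protein response, cholesterol biosynthesis and sex-specific genes, the median, the mean and the camera direction differed in sign. The lysosome list passed without deleted a (0.0393), and that of primary granules without control b (0.0329).

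No chromosome's number of changed genes passed its test. Chromosome 2 held the largest share, 7.69% of the 286 (22 genes), and a permutation test of the largest share gave p = 0.995, which speaks only for gene-rich chromosomes since these set that share. Chromosome X held 19 changed genes where chance would give 10.6 (Fisher's exact test, p = 0.0165, adjusted p = 0.270).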

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

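The fit of rows that name several genes together with all named rows was chosen after a fit beside the unnamed rows had given 0 calls. These rows were outside the test of the 19938 genes, of which 3164 had an unadjusted p under 0.05. Of 1621 such rows fitted with all named rows, 10 passed an adjusted p of 0.05 in limma, 3 higher and 7 lower after deletion. In that fit, 313 (19.3%) had an unadjusted p under 0.05. Fitted beside the unnamed rows, 168 (10.4%) did and 0 passed. The 10 calls therefore depend on which rows shared the fit. Of 12146 unnamed rows fitted alone, 0 passed and 1403 (11.6%) had an unadjusted p under 0.05. No gene is named from these rows, since each reads several.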

How the results depend on the processing

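All alternatives were chosen before the data were examined, except the list test without Cebpa with an estimated correlation, chosen after seeing the data. Among genes at or above the median of mean intensity 438 genes changed, 235 of them higher, with 240 shared with the 286, fewer genes being tested. Centring arrays on the median gave 231 higher. The medians of control arrays (6.22 to 6.23) lay above those of deleted arrays (6.16 to 6.20). Centring therefore moved all log2 fold changes up by the same amount, and their median went from 0.03 to 0.08. Testing every deposited row gave 13 (4 higher, 9 lower; 8 shared) and left Cebpa at -1.71 with an adjusted p of 0.0513; the prior then had 2.25 degrees of freedom instead of 5.52. An adjusted p under 0.10 gave 676 (360 higher, 316 lower). The ordinary pooled-variance test, which shares no variance between genes, gave 0 changed, 0 higher and 0 lower, and Cebpa at -1.71 with an adjusted p of 0.187. Leaving out each array gave 53 to 250 changed genes, 28 to 135 higher and 25 to 115 lower, with fewer samples. With an estimated correlation 0 lists passed, with Cebpa in the lists or without it. The estimate was -0.026 for the mature neutrophil list and -0.013 for the dendritic cell list, below the preset 0.01. For these lists, a higher correlation between members is argued against as the cause. The estimate was 0.032 for the stem cell list and 0.043 for the ribosomal list, above the preset value. No other cause was tested. The other settings gave 255 to 351 changed genes, and 3 to 5 lists passed in the other settings run for lists. Cebpa lay between -1.85 and -1.57 and passed in all settings but those named. Over all settings, values of named genes stayed on their side of the threshold 619 times, lost a call 130 times and gained one 20 times, and no direction reversed. Only 31 of the 43 named genes were called, so the 619 include genes with no call to lose. The genes were picked for large changes or small p, so a reversal was unlikely. Every deposited row, the robust prior and the ordinary test were not run for lists. Without detection calls, dim genes cannot be told from background.

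The letters of the sample titles are shared by the genotypes, but nothing in the labels pairs the mice. Deviations from the group means correlated at -0.01 for a, -0.04 for b and 0.06 for c, and only control c correlated best with its own letter. With the letters as a replicate block 274 genes changed (127 higher, 147 lower), and 4 lists passed. Among named genes the block ended the call of Rps14 (adjusted p = 0.0551) and began those of Cox6a2 (0.0399) and H2-DMa (0.00825).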

Other observations

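Genes in the first 3 paragraphs were chosen after their values were seen, as were the tests of array scaling, of the interferon list, of array quality and of short-RNA recovery; the other tests were written before their results were seen. Among changed genes outside the lists or not yet described, the transcription factors Zbtb16 (log2 0.84 ± 0.13 SE), Tox (0.80 ± 0.10) and Runx3 (0.71 ± 0.10), which act in lymphocyte development, rose after deletion (n = 3 per genotype, limma adjusted p = 0.0163, 0.00929 and 0.0119). The C-type lectin genes Clec4e (1.57 ± 0.19), Clec2i (1.56 ± 0.21), Clec4d (0.86 ± 0.13) and Clec10a (0.67 ± 0.13) rose, as did the kinase genes Pim2 (0.84 ± 0.13) and Pim1 (0.69 ± 0.13). Hk3, a hexokinase (-1.50 ± 0.12), Tfec, a transcription factor (-1.22 ± 0.20), Dusp6, a phosphatase of ERK kinases (-1.06 ± 0.20), and Cyba, a subunit of the NADPH oxidase of phagocytes (-0.88 ± 0.16), fell. No enrichment was tested for these groups.

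The X-linked genes Bex1 (-1.34 ± 0.13), Tceal5 (-1.14 ± 0.16) and Maged1 (-0.99 ± 0.12) fell, but of 19 changed genes on chromosome X 9 were higher and 10 lower, and their number did not pass (Fisher's exact test, adjusted p = 0.270). Mir103-2 fell by 2.44 ± 0.36, with control values varying by 0.86 (SD, n = 3). Of 54 small nucleolar RNA rows, 43 had a negative log2 fold change, with a median of -0.36. Snora3 (-1.53 ± 0.17), Snora44 (-1.20 ± 0.24) and Snora69 (-1.15 ± 0.21) fell and none rose.

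The labels call the mice female. Xist, transcribed from the inactive X chromosome of female cells, read between 4.46 and 5.13 on the 6 arrays, percentiles 18.3 to 28.5 of each array. The Y-linked genes Kdm5d (8.07 to 8.48), Eif2s3y (8.04 to 8.49) and Uty (6.60 to 7.23) read at percentiles 82.3 to 85.7, 81.9 to 85.7 and 58.1 to 70.7. Dim Xist with bright Kdm5d and Eif2s3y on all 6 arrays argues against the label. The list of sex-specific genes did not pass camera (adjusted p = 0.863), a test that compares the genotypes and does not bear on the label.

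S100a8 and S100a9 fell more than 10-fold. Scaling between arrays is argued against, since the smaller fall stayed at -3.32 under 3 other normalizations. The median of 8 neutrophil granule genes was -0.22 (95% bootstrap interval -0.61 to 0.05), above the -1 that fewer mature neutrophils, or less of their RNA, in the sorted cells was set in advance to need. That bound was judged out of reach after the value was seen, because Ltf, Lcn2, Retnlg, Mmp8 and Chil3 read between 4.42 and 5.39 in controls, near the 4.88 to which S100a8 fell, while of the brighter genes Camp had -0.97, Ngp -0.61 and Cd177 -0.10. Neutrophil RNA, which the sort for LSK cells would remove, and lower expression in progenitors that lack Cebpa therefore cannot be told apart.

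Ifi206, Ifi209 and Ifi214, neighbours on chromosome 1, rose with Cd48, so that a window of 50 genes held 4 changed genes, all higher. Chance placement of changed genes could account for the density of such a window. The densest window of all held 5 and the 95th percentile in shuffles was 6. A window this wide cannot judge the Ifi200 family itself, which was noticed through its rises. Of 9 family rows tested 3 changed, with a family median of 0.54, against 286 of 19853 genes. As a list, the type I interferon genes did not rise by as much as this family. Their median was 0.10 (95% bootstrap interval 0.00 to 0.17, members resampled as if independent) and 0.03 to 0.18 over the alternatives. A smaller interferon response stays open as a cause. Of 35 members 24 had a positive log2 fold change, and camera called the list without deleted b or deleted c. A chromosome segment of another strain in one genotype cannot be excluded: only 1 changed gene of the window lay outside the Ifi200 family, but a segment with few differing genes would not exceed 6, so that bound was too strict. Cross-hybridisation within the family stays open, since the window was no denser than chance with the family included.

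Ribosomal protein and small nucleolar RNA rows were lower together. For small nucleolar RNAs scaling is argued against, with a median of -0.30 nearest 0 under 3 other normalizations, whereas for ribosomal proteins it stays open, with a median of -0.0523 nearest 0 and a highest camera adjusted p of 0.00167. A single lower-quality array is argued against, since the class median nearest 0 was -0.16 whichever array was left out. Lower recovery of short RNAs was not tested for ribosomal proteins, and for small nucleolar RNAs it cannot be told apart, since microRNA rows had a median of 0.00107 but only 26% of them read at or above the median of all values. A biological difference between the genotypes was not tested.

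The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 286 genes, the highest other 1, so 1 split gave as many genes. For gene lists the real split gave 4 and the highest other 8, and 3 splits gave as many lists. The split with 8 put controls a and b with deleted a, and why it gave more lists was not tested.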
